A study of Homo sapiens with 6 samples.

How the data were processed

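RNA was measured in 6 cultures of HepG2, a line of human liver cancer cells that keeps the expression of many hepatocyte genes. Per the labels, 3 libraries came from control cells and 3 from cells given 10 µM tamarixetin, an O-methylated form of the dietary flavonol quercetin, for 24 h. The labels call the samples of each group biological replicates. They give no treatment for the controls and name neither a vehicle nor, separately, the medium of the control cells. Per the labels' protocols, the compound was given in medium with 1% serum, against 10% for growth, and the serum of the control cultures during those 24 h is not stated. Per the labels' protocols, libraries were made with the Lexogen QuantSeq 3′ kit (forward version), which reads the part of an mRNA next to its poly(A) tail, so that a count stands for about 1 fragment per transcript whatever the transcript's length.

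Per the submitters' processing notes, fastp 0.23.1, STAR 2.7.10b and featureCounts 2.0.6 were used with the GRCh38 genome. The annotation release, the strand setting of the counting and any use of molecular identifiers are not given in the sources used here. The deposited values are raw counts per gene symbol, not normalised, in 1 table per library with the same 43424 symbols. Of these symbols, 42739 were found in the RefSeq gene table for GRCh38.p14, from which gene coordinates were taken. A total of 38 symbols carry the ending _1 and stand for a further copy of a gene. Reads of near-identical genes can be split or lost in such counting, so the values of single metallothionein, AKR1C, UGT2B, tubulin and HSPA1A or HSPA1B genes are uncertain, and so are those of genes that overlap another gene.

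Total counts per library ran from 11980585 to 16168855, and between 18291 and 19003 genes had at least 1 count. Library pairs of the same group differed by a chi-square of 2.37 to 3.52 per gene (6 pairs), above the sampling noise of counts, and pairs across the groups by 40.3 to 51.4 (9 pairs), so that no library was treated as a copy of another. The common biological coefficient of variation was 4.70%.

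Genes were tested with edgeR 4.0.16 in R 4.3.3: low counts were removed with filterByExpr, libraries were scaled with TMM factors, and tamarixetin was compared with control in a quasi-likelihood F test with group as the only term. The p-values were adjusted by the Benjamini-Hochberg method over the 13198 genes tested, with a threshold of 0.05 and no fold minimum. Standard errors (SE) of log2 fold changes were taken as the fold change divided by the square root of F. CPM values are counts scaled to the TMM-adjusted library sizes. Counts were simulated with the means and library sizes of this comparison, with 200 genes changed and 13038 genes passing the filter. The test recovered 56% of 50 genes changed 1.25-fold, 68% of 50 changed 1.5-fold, 92% of 50 changed 2-fold and 98% of 50 changed 3-fold. There were 8 false calls.

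A set of 33 gene lists was written from general knowledge of hepatocyte and HepG2 biology and from the title of the series. The lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2. A preset correlation of 0.01 between genes was used, and p was adjusted over the 33 lists. The lists overlap in part and do not count as independent. Each list was also tested with a correlation estimated from the libraries, and with fry, which asks if the genes of a list move one way and does not compare them with other genes; fry called 25 lists, 16 higher and 9 lower. The rule for naming single genes took 3 sources: the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 10 CPM and no overlap between the groups, 20 genes of the axis named in the title of the series whatever their values, and up to 4 members of each list with the smallest p. A few genes that the rule takes are not reported here. All of these choices were made before the data were examined. Members named because they are the few that moved against the rest of their list were chosen after their values were seen, as were RNR1, the other mitochondrial RNAs outside the coding genes, and the genes and lists first named in the observations.

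Alternatives covered scaling by DESeq2 size factors or by library size alone, no filter or a filter of at least 5 CPM in 3 libraries, the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0 and limma-voom, an adjusted p of 0.01, a minimum fold of 1.2, and lists without the genes they share. Scaling by the upper quartile and leaving out the mitochondrial genes other than RNR1 were added after the data were seen.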

Results

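The series asks how tamarixetin changes the transcriptome of HepG2 cells, and its title centres on SLC7A11, GPX4 and NRF2. Expression was counted in 3 control and 3 tamarixetin libraries (10 µM, 24 h). Tamarixetin was given in medium with 1% serum, and the serum of the control medium is not stated, so each difference is one between these cultures and a serum difference between them is not ruled out. The control libraries held 14699739, 12131365 and 16168855 counts and the tamarixetin libraries 15454815, 13661767 and 11980585. Mitochondrial transcripts made up 10.6% ± 0.390 of the counts in control and 8.23% ± 0.278 in tamarixetin libraries (SD, n = 3 each).

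Tamarixetin was followed by a strong rise of CYP1A1, a cytochrome P450 under control of the aryl hydrocarbon receptor (chromosome 15, 74719542 to 74725528), from 1.53 ± 0.873 to 342 ± 8.57 CPM (SD, n = 3 per group). Among genes with a mean of at least 10 CPM, the next largest rises were in SLC16A6, a monocarboxylate transporter family member (log2 fold change 4.77, SE 0.112), AQP3, a water and glycerol channel (4.41, SE 0.119), the glycerolipid enzyme GPAT3 (3.13, SE 0.127), the aldo-keto reductase AKR1B10 (3.07, SE 0.107) and the Ras activator SOS1 (2.89, SE 0.043). RGMB, a co-receptor for bone morphogenetic proteins, the metal-binding protein MT2A, the long noncoding RNA LINC00511 and the G-protein regulator RGS10 rose by 2.88, 2.68, 2.67 and 2.62 on the log2 scale. MT2A was already abundant in control cells, at 764 ± 28.6 CPM, and reached 4905 ± 75.6 CPM.

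The largest fall among genes of that level was in FGA, the fibrinogen alpha chain secreted by hepatocytes (chromosome 4, 154583126 to 154590742), from 575 ± 12.1 to 104 ± 1.32 CPM, a log2 fold change of -2.47 (SE 0.040). PLPPR1 (-2.46), the glucuronosyltransferase UGT2B10 (-2.43), the galectin LGALS2 (-2.41) and the glutamate transporter SLC1A2 (-2.12) followed. SLC23A1, a vitamin C transporter, SLC5A9, a sugar transporter, CLDN19, a tight junction protein, the apolipoprotein APOC3 and the imprinted gene PEG10 had log2 fold changes of -2.05, -2.03, -1.90, -1.89 and -1.86. PEG10 was among the abundant genes of control cells, at 2071 ± 16.2 CPM, and stood at 569 ± 4.05 CPM with tamarixetin. Across these 20 genes the adjusted p ran from 3.35e-89 to 1.12e-22 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjustment), and each had all 3 tamarixetin libraries on one side of all 3 controls.

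In all, 5771 of 13198 genes tested changed (43.7%), 2954 higher and 2817 lower. The groups did not overlap in 6665 genes (50.5%), where chance gives 10%. Most changes were small: 802 genes changed at least 2-fold, 445 up and 357 down. With a minimum fold of 1.2 built into the test, 2560 genes passed.

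**Figure D1:**
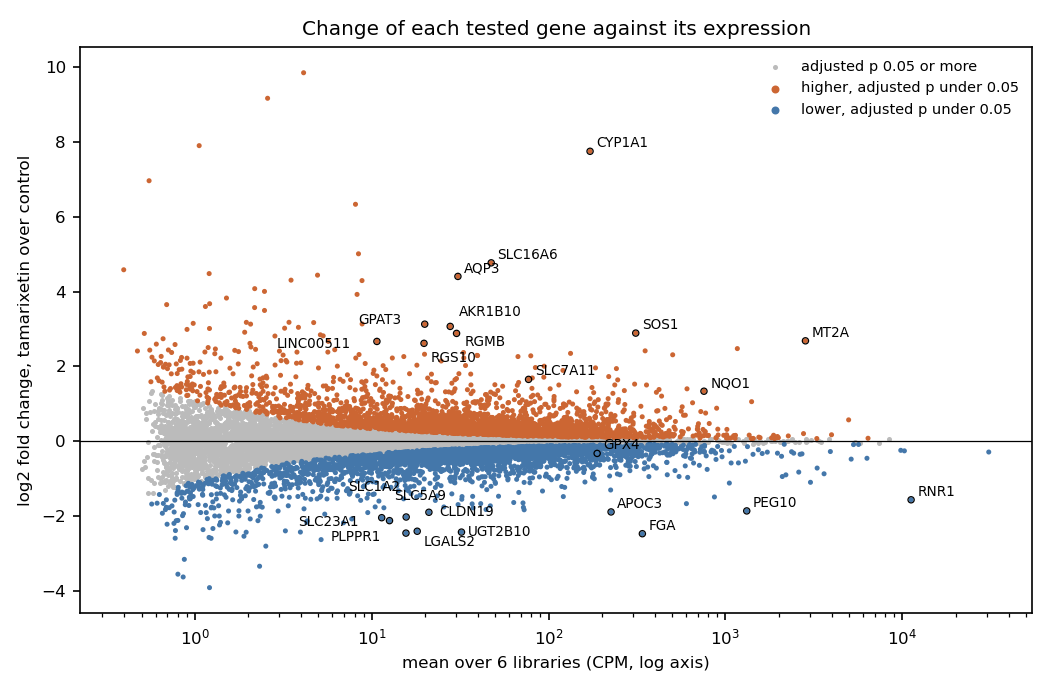
Log2 fold change, tamarixetin over control, of each of the 13198 genes tested (vertical) against its mean over the 6 libraries in CPM on a log axis (horizontal). Colour marks genes past an adjusted p of 0.05; the labelled points are the 20 genes with the largest rises and falls among those with a mean of at least 10 CPM and no overlap between the groups, and 4 others. CYP1A1 stands at 7.75 and FGA at -2.47; the points above CYP1A1 have means under 10 CPM, CYP1A2 with 0 counts in the controls among them.

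The genes of the axis named in the title moved in both directions. SLC7A11, the cystine importer (chromosome 4, 138164097 to 138242349), rose from 37.3 ± 3.52 to 117 ± 2.89 CPM, a 3.14-fold difference (log2 fold change 1.65, SE 0.062), and its partner chain SLC3A2 rose by 1.14 (SE 0.043). GPX4, the selenoenzyme that reduces lipid hydroperoxides (chromosome 19, 1103994 to 1106779), fell from 209 ± 8.70 to 167 ± 5.84 CPM, a log2 fold change of -0.33 (SE 0.043, adjusted p = 3.37e-10 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with every tamarixetin library under every control library. NFE2L2, which encodes NRF2, rose 1.19-fold (log2 0.25, SE 0.042), and KEAP1, which encodes the repressor of NRF2, rose 1.50-fold (log2 0.59, SE 0.058).

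Several enzyme genes of this set had larger rises than NFE2L2 itself, though GPX4 fell. GCLM rose by 1.97 and GCLC by 1.57, the subunits of the rate-limiting enzyme of glutathione synthesis. TXNRD1 (thioredoxin reductase) rose by 1.89, SRXN1 (sulfiredoxin) by 1.94 and the quinone reductase NQO1 by 1.34, from 429 ± 15.9 to 1084 ± 25.1 CPM. HMOX1, the heme oxygenase, rose by 0.34 (SE 0.090), AIFM2, a GPX4-independent ferroptosis suppressor, by 0.44, ATF4 by 0.33 and the transferrin receptor TFRC by 0.24. ACSL4, which activates polyunsaturated fatty acids for use in phospholipids (-0.33), and the ferritin heavy chain FTH1 (-0.14) fell. The ferritin light chain FTL, at 3478 ± 28.2 CPM in control and 3420 ± 59.4 CPM with tamarixetin, did not pass the test (log2 fold change -0.024, adjusted p = 0.499, edgeR with Benjamini-Hochberg adjustment), and its sign turned with scaling by library size alone (0.011). CHAC1 and PTGS2, common markers of ferroptosis, had too few counts to be tested.

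Of the 20 axis genes 18 were tested, 13 rose and 4 fell, and 17 changed when adjusted over the list alone. The list follows the title of the series, which may rest on these samples, so its direction is not independent evidence.

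**Figure D2:**
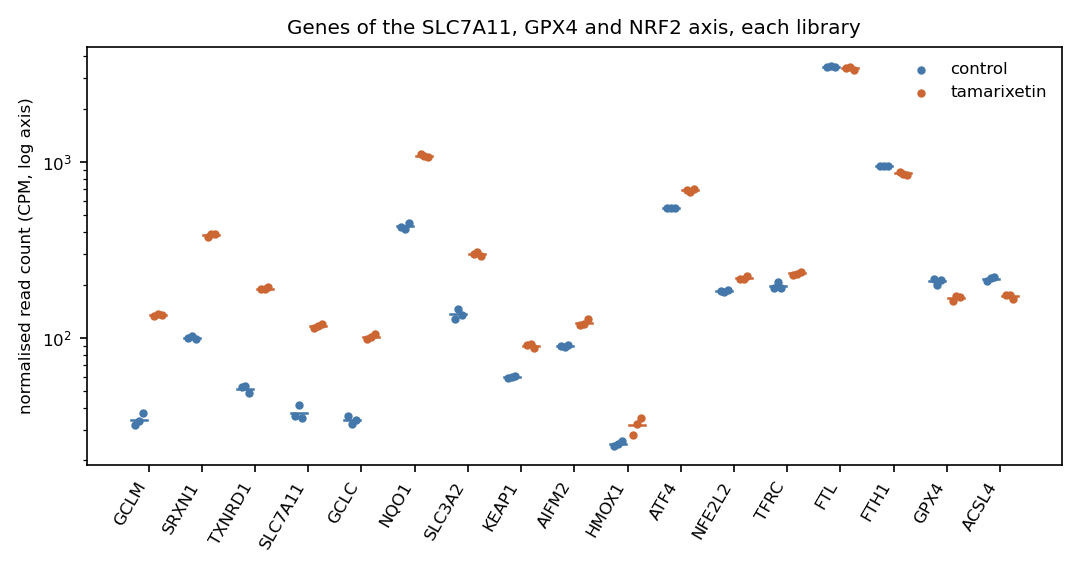
Normalised read count in CPM on a log axis for 17 genes of the axis, 1 point per library (3 control, 3 tamarixetin) with the group mean as a bar, ordered by log2 fold change. SLC7A11 rises from a mean of 37.3 to 117 CPM and GPX4 falls from 209 to 167 CPM.

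Of the 33 lists, camera called 17, with 12 higher and 5 lower. NRF2 targets stood first: of 31 tested, 25 rose and 3 fell, 28 changed adjusted over the list alone, and the median log2 fold change was 0.93 (camera adjusted p = 2.81e-11). This was the single list whose call held when the correlation was estimated (adjusted p = 0.0457 with an estimated correlation). The autophagy receptor SQSTM1 rose by 1.64 and the aldo-keto reductase AKR1C1 by 1.40, beside SRXN1 and NQO1. PRDX1 (-0.26), GPX2 (-0.19) and FTH1 were the 3 that fell. NRF2 is named in the title of the series, which may rest on these samples, and the list shares genes with the axis set. The call of this list is therefore not independent evidence.

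Aryl hydrocarbon receptor targets had the highest median, 1.36, with 6 of 8 tested higher and none lower, and 8 higher adjusted over the list alone (camera adjusted p = 1.04e-06; adjusted p = 0.0669 with an estimated correlation). CYP1A2, the neighbour of CYP1A1, had 0 counts in the controls and 8.24 ± 0.269 CPM with tamarixetin, at least 117-fold higher against a floor of 3 counts over the control group. At that bound CYP1A2 still lies above the median, so the median of 1.36 could not change. The median lies between NQO1 (1.34) and the amino acid transporter SLC7A5 (1.38) of the same list. Both also stand in another list, NQO1 among NRF2 targets and SLC7A5 in the integrated stress response. AHRR and UGT1A6 had 0 counts and were not tested, nor was SERPINB2, which had low counts. PXR and CAR targets, genes of drug disposition, were higher in 5 of 7 and lower in none, with 6 higher adjusted over the list alone and a median of 0.79. The drug exporters ABCB1 (1.41) and ABCC2 (0.98) and the sulfotransferase SULT2A1 (0.79) led them (camera adjusted p = 5.16e-04; adjusted p = 0.0669 with an estimated correlation).

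Genes of the integrated stress response, the programme of the transcription factor ATF4, rose in 27 of 31 and fell in 1, ALDH18A1 (-0.39), with 29 changed adjusted over the list alone and a median of 0.44. SLC7A5, SLC7A11, SLC3A2 and the hormone gene STC2 (0.99) had the smallest p (camera adjusted p = 3.03e-09; adjusted p = 0.0669 with an estimated correlation). Heat shock genes rose in 18 of 20 and fell in 1, HSPB1 (-0.34), and 19 changed adjusted over the list alone. The chaperones HSPA1A (1.05), HSPH1 (0.91), HSPA1B (0.80) and HSPA8 (0.63) were the examples, with a list median of 0.40 (camera adjusted p = 6.14e-06; adjusted p = 0.0669 with an estimated correlation). Metallothioneins and zinc response genes rose in 7 of 9, with MT1F (-0.33) lower and 8 changed adjusted over the list alone. Their median was 0.71, and MT1E (1.50), MT1A (2.14) and MT1X (0.71) rose beside MT2A (camera adjusted p = 1.69e-04; adjusted p = 0.0669 with an estimated correlation).

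In contrast to these stress lists, the unfolded protein response of the endoplasmic reticulum was lower. Of 21 members 13 fell and 3 rose (DNAJB11, CANX and HYOU1, by 0.31, 0.081 and 0.11), 17 changed adjusted over the list alone, and the median was -0.21. The chaperones CALR (-0.58), HSP90B1 (-0.42), PDIA4 (-0.51) and HSPA5 (-0.32) had the smallest p (camera adjusted p = 0.00149; adjusted p = 0.0669 with an estimated correlation).

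Genes that mark hepatocytes fell in 22 of 28 and rose in 3 (AMBP 0.16, APOA2 0.17 and TAT 0.67), with 25 changed adjusted over the list alone and a median of -0.58 (camera adjusted p = 2.54e-09; adjusted p = 0.0669 with an estimated correlation). Besides FGA and APOC3, the fibrinogen gamma chain FGG (-1.67) and the plasma glycoprotein APOH (-1.49) fell. Cholesterol synthesis genes fell in 21 of 25 and rose in none, 21 changed adjusted over the list alone, and the median was -0.56. HMGCS1, which makes the precursor of mevalonate, fell by 0.93, and the squalene epoxidase SQLE by 0.84 on the log2 scale (camera adjusted p = 1.66e-09; adjusted p = 0.0669 with an estimated correlation).

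DNA replication genes of G1 and S phase fell in 24 of 30, with CCND1 higher (0.40) and 28 changed adjusted over the list alone. The median was -0.39, and the ribonucleotide reductase subunits RRM2 (-0.68) and RRM1 (-0.52) and the helicase subunits MCM5 (-0.80) and MCM2 (-0.52) had the smallest p (camera adjusted p = 9.34e-09; adjusted p = 0.0669 with an estimated correlation). G2 and M phase genes were mixed: 9 of 30 rose, 10 fell, 20 changed adjusted over the list alone, and the median of -0.0039 turned to 0.031 with scaling by library size alone (camera adjusted p = 0.728). TOP2A (-0.40), NUSAP1 (-0.67) and CDK1 (-0.39) fell and PTTG1 (0.50) rose. The mean log2 CPM of G1 and S genes minus that of G2 and M genes was -0.28 ± 0.042 in control and -0.66 ± 0.0062 in tamarixetin libraries, a difference of -0.38 (exact permutation test, two-sided p = 0.1, n = 3 per group, the smallest p that 3 against 3 allows).

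Ribosome biogenesis genes rose in 24 of 26 and fell in none, 24 changed adjusted over the list alone, and the median was 0.41. The RNA helicase DDX21 (0.79), the rRNA processing factors RRP9 (0.98) and RRS1 (0.65) and the methyltransferase NOP2 (0.73) led them (camera adjusted p = 3.03e-09; adjusted p = 0.0669 with an estimated correlation). Immediate early genes, which growth factor signals induce, rose in 19 of 23, with CCN2 lower (-0.20) and 21 changed adjusted over the list alone. Their median was 0.87, with CCN1 (2.26), DUSP6 (1.08), KLF6 (0.99) and IER3 (0.88) as examples (camera adjusted p = 6.80e-08; adjusted p = 0.0952 with an estimated correlation). Ribosomal protein genes moved little. Of 55, 13 rose and 2 fell (RPS20 by 0.15, RPL28 by 0.12), 13 changed adjusted over the list alone, and the median of 0.024 turned to -0.011 with upper quartile scaling (camera adjusted p = 0.253, and 0.0408 with scaling by library size alone).

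Lysosome and autophagy genes rose in 15 of 23 and fell in 3 (NBR1 -0.53, ULK1 -0.32 and CTSD -0.16), with 18 changed adjusted over the list alone and a median of 0.22. SQSTM1, NEU1 (0.52) and CTSA (0.50) were among those with the smallest p (camera adjusted p = 0.00228; adjusted p = 0.142 with an estimated correlation). Acute phase and NF-kB targets rose in 6 of 14 tested and fell in 1, NFKBIA (-0.23). Of these, 7 changed adjusted over the list alone, and the median was 0.26. The other members, among them CXCL1, IL6, CCL2, SAA1, CRP and LCN2, had too few counts to be tested. SERPINA3 (1.28), TNFAIP2 (1.76) and the chemokine CCL20 (0.72) rose (camera adjusted p = 0.00946; adjusted p = 0.149 with an estimated correlation). This call was lost without the filter on low counts (camera adjusted p = 0.0599).

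Glutathione genes and p53 targets passed by little (camera adjusted p = 0.0430 for both; adjusted p = 0.142 with an estimated correlation for both). Of 23 glutathione genes 12 rose and 6 fell, 19 changed adjusted over the list alone, and the median was 0.25. The glutathione transferases MGST1, GSTO1 and GSTP1 rose by 1.35, 0.54 and 0.60, next to GCLM, GCLC and SLC7A11, while 5 other transferases fell, MGST2 (-0.79), GSTA1 (-1.08), MGST3 (-0.47), GSTK1 (-0.43) and GSTA4 (-0.40), and so did the glutamyltransferase GGT1 (-1.37). Of 30 p53 targets 15 rose and 4 fell (DDB2 -0.50, SESN1 -0.40, FDXR -0.34 and PPM1D -0.28), 19 changed adjusted over the list alone, and the median was 0.14. The stress cytokine GDF15 rose by 2.48, from 356 ± 19.4 to 1980 ± 100.1 CPM, the cell cycle inhibitor CDKN1A by 0.88, GADD45A by 0.71 and SESN2 by 0.63. The glutathione call was lost without tamarixetin replicate 1 (camera adjusted p = 0.0503) or 3 (0.0556), with scaling by library size alone (0.0582) and with at least 5 CPM in 3 libraries (0.101), and its median was -0.079 without genes that stand in another list. The p53 call was lost without control replicate 1 (camera adjusted p = 0.0604) or 2 (0.0577), without tamarixetin replicate 1 (0.0503) or 3 (0.0539), with upper quartile scaling (0.0529), with at least 5 CPM in 3 libraries (0.0697) and without shared genes (0.0591).

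The 13 coding genes of the mitochondrial genome fell in 9 and rose in none, 9 changed adjusted over the list alone, and the median was -0.28 (camera adjusted p = 0.00141; adjusted p = 0.427 with an estimated correlation). COX3 (-0.48), ATP6 (-0.46), ATP8 (-0.53) and CYTB (-0.34) had the smallest p. The 12S ribosomal RNA RNR1 fell by more than each of the coding genes, from 16770 ± 254.2 to 5661 ± 124.6 CPM (log2 fold change -1.57, SE 0.025). The 16S ribosomal RNA RNR2 fell by 0.29, while TRNF and TRNL1, the tRNA genes at the outer ends of the ribosomal RNA pair, rose by 0.53 and 0.47. Of 13 mitochondrial tRNA genes tested these 2 rose and 5 fell. TRNP fell from 36.9 ± 1.62 to 18.4 ± 2.22 CPM, TRNM (-0.82) from 19.2 CPM and TRNY (-0.45) from 39.1 CPM. TRNH (-1.39, SE 0.302) and TRNA (-1.15, SE 0.443) had low counts, at 3.76 and 1.72 CPM in control. Reads that run over a boundary between neighbouring mitochondrial genes can be counted in either. The mitochondrial share of all counts was 10.6% in control and 8.23% in tamarixetin libraries. Nuclear genes of the respiratory chain were mixed: of 37, 5 rose and 13 fell, 18 changed adjusted over the list alone, with a median of -0.066 (camera adjusted p = 0.305). NDUFV2 (0.73) and NDUFV1 (0.51) rose and ATP5F1A (-0.24) fell.

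**Figure D3:**
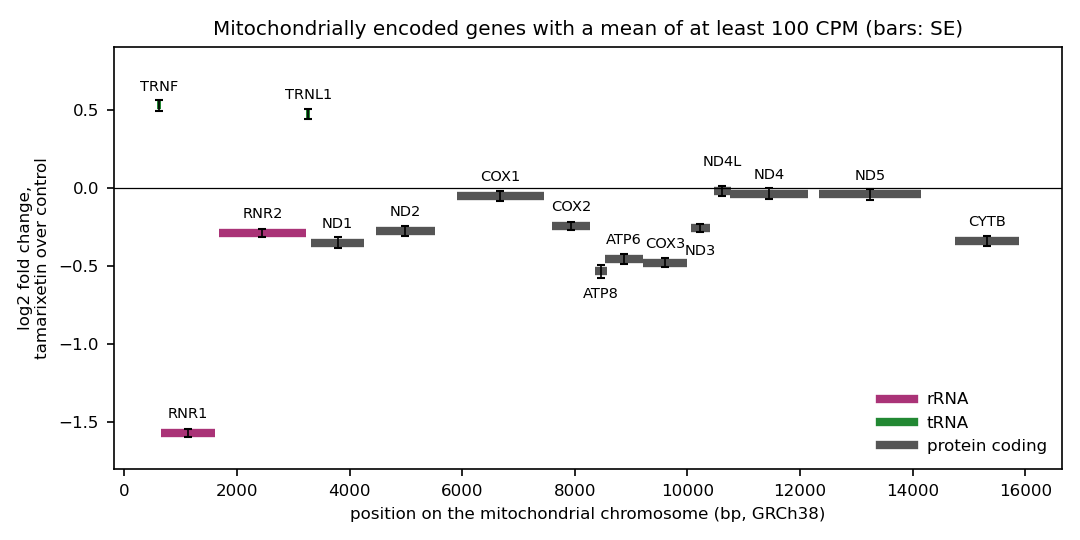
Log2 fold change, tamarixetin over control (vertical), of the 16 mitochondrially encoded genes with a mean of at least 100 CPM, drawn at their position on the mitochondrial chromosome in bp (horizontal; thin bars are the SE). RNR1 lies at -1.57, its neighbour RNR2 at -0.29 and TRNF at 0.53.

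The 4 lists of ferroptosis, selenium and iron genes did not pass in camera, while fry, which does not compare a list with other genes, called ferroptosis defence higher (adjusted p = 3.41e-05), ferroptosis drivers higher (0.00166) and iron handling lower (0.00130), and not selenoproteins (0.0795). Ferroptosis defence genes rose in 8 of 20 and fell in 3 (GPX4, EEFSEC -0.32 and SC5D -0.31), 11 changed adjusted over the list alone, and the median was 0.092 (camera adjusted p = 0.0642). They passed without control replicate 2 (camera adjusted p = 0.0406) and without the filter on low counts (0.0440). Ferroptosis drivers rose in 6 of 13 and fell in 3, and 9 changed adjusted over the list alone. Their median was -0.017 (0.018 with scaling by library size alone) and their mean 0.12, and camera's direction was up (adjusted p = 0.434). SAT1, a polyamine acetyltransferase, rose by 1.04, and the ferritinophagy receptor NCOA4 (-0.39) fell with ACSL4. Selenoproteins rose in 4 of 21 and fell in 9, with 14 changed adjusted over the list alone and a median of -0.14 (camera adjusted p = 0.426). TXNRD1 and the selenophosphate synthetase SEPHS2 (0.56) rose, and GPX3 (-0.71) fell with GPX4. Iron handling genes rose in 5 of 20 and fell in 9, 14 changed adjusted over the list alone, and the median was -0.050 (camera adjusted p = 0.253). The iron hormone HAMP rose by 1.32, and transferrin TF (-0.95) and the metal importer SLC39A14 (-0.47) fell.

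Lists of lipid and energy metabolism held strong changes in both directions without a call. Fatty acid oxidation and PPARA targets rose in 5 of 20 and fell in 10, with 15 changed adjusted over the list alone. CPT1A, which carries fatty acids into mitochondria, rose by 1.96, from 75.3 ± 1.38 to 293 ± 7.44 CPM, and the lipid droplet protein PLIN2 by 1.31, while FABP1 (-0.79) and HADHB (-0.44) fell. The median was -0.17 and the mean 0.034, with camera down (adjusted p = 0.253) and fry up (adjusted p = 0.0166). Fatty acid synthesis genes rose in 3 of 18 and fell in 8, 12 changed adjusted over the list alone, and the median was -0.15 (camera adjusted p = 0.0592). SLC25A1 (-0.56), PNPLA3 (-0.94), MLXIPL (-0.36) and DGAT2 (-0.48) fell. That list passed without control replicate 1 (camera adjusted p = 0.0428), without tamarixetin replicate 2 (0.0474) and without the filter on low counts (0.0354). Hypoxia and glycolysis genes rose in 6 of 24 and fell in 10, 16 changed adjusted over the list alone, with a median of -0.15 (camera adjusted p = 0.397). The glucose transporter SLC2A1 (0.82) and the peptide ADM (1.27) rose, and P4HA1 (-0.84) and BNIP3L (-0.75) fell. FOXO targets rose in 5 of 21 and fell in 8, 13 changed adjusted over the list alone, with a median of -0.11, a mean of 0.030 and camera down (adjusted p = 0.629). Among them IGFBP1 rose by 2.42 and TXNIP (-0.95) fell.

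Apoptosis regulators rose in 10 of 23 and fell in 3, CFLAR, APAF1 and CASP9, 13 changed adjusted over the list alone, and the median was 0.20 (camera adjusted p = 0.0648, and 0.0368 without the filter on low counts). PMAIP1 (1.03), BMF (0.86), CYCS (0.53) and XIAP (0.39) rose. Interferon response genes rose in 5 of 24 and fell in 5, 10 changed adjusted over the list alone, with a median of 0.099 (camera adjusted p = 0.581). OAS1 (1.24) rose and IFI35 (-0.72) fell.

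Markers of other cell types gave no common direction. Biliary and progenitor markers rose in 2 of 11 and fell in 6, 8 changed adjusted over the list alone, with a median of -0.19 (camera adjusted p = 0.228). SPP1 (1.21) rose, and the fetal liver marker GPC3 (-0.33), LGR5 (-0.96) and KRT19 (-0.34) fell. Mesenchymal and stellate markers rose in 3 of 13 and fell in 5, 8 changed adjusted over the list alone, with a median of -0.063, a mean of 0.033 and camera down (adjusted p = 0.728). CDH2 (-0.67) fell and TAGLN (0.49) rose. Of 16 blood and endothelial markers 6 had enough counts to be tested, 1 rose and 3 fell, 4 changed adjusted over the list alone, with a median of -0.032 that turned to 0.0032 with scaling by library size alone (camera adjusted p = 0.629). LYZ (-0.26) was the abundant one, at 936 ± 52.7 CPM in control and 781 ± 28.6 CPM with tamarixetin.

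**Figure D4:**
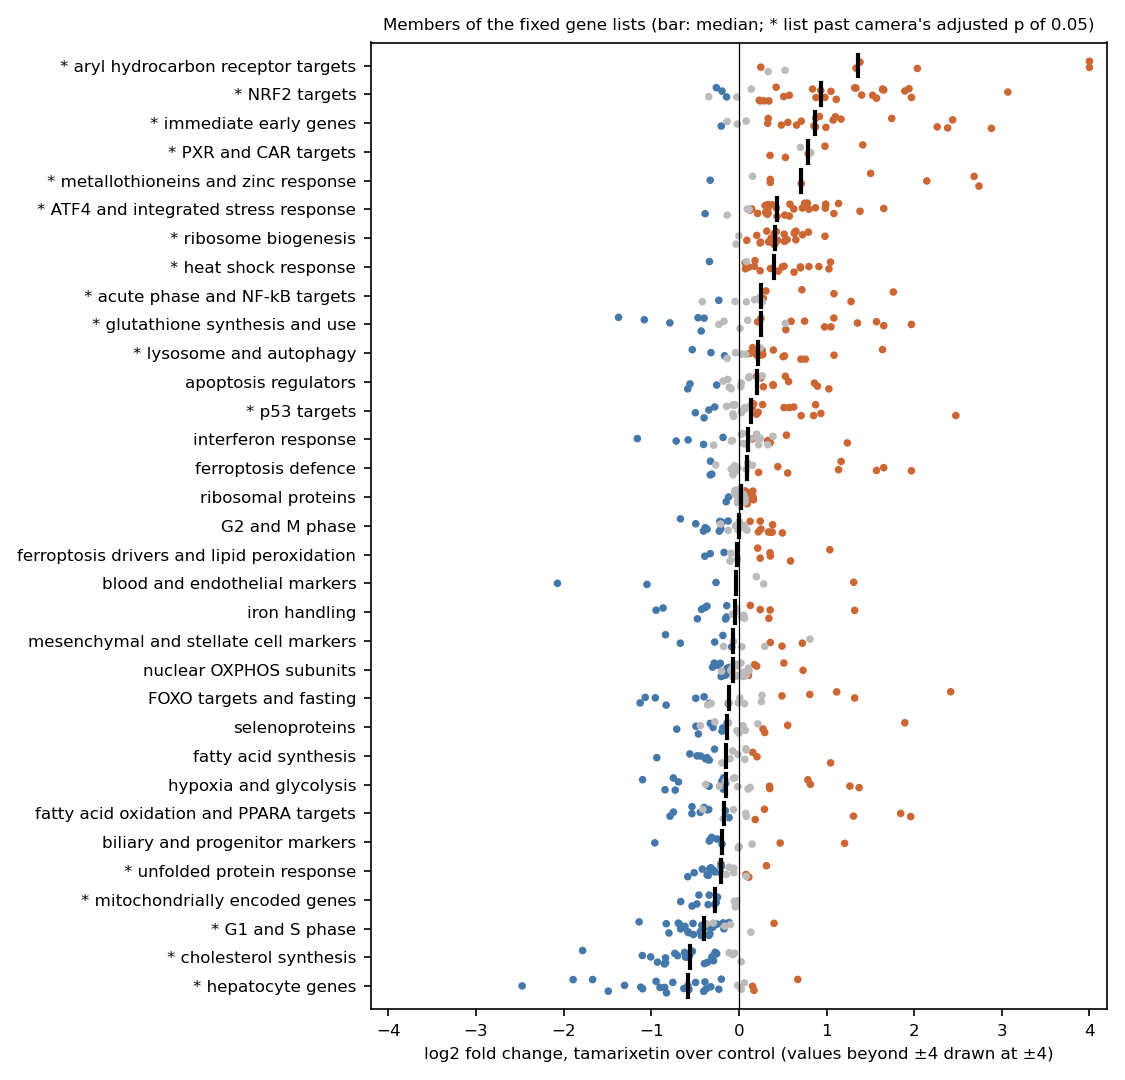
Log2 fold change, tamarixetin over control, of each tested member (points; orange higher and blue lower past an adjusted p of 0.05, grey not) of the 33 lists, with the median of each list as a bar. Points beyond 4 on the log2 scale are drawn at 4, and the medians run from 1.36 for aryl hydrocarbon receptor targets to -0.58 for hepatocyte genes.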

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

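Upper quartile scaling and leaving out mitochondrial genes were chosen after the data were seen. With a minimum fold of 1.2 in the test, 2560 genes changed, 1319 higher and 1241 lower, since that test asks for more than a difference from 0. With an estimated correlation camera called 1 list, 1 higher and 0 lower, where 8 higher and 4 lower had an unadjusted p under 0.05. The estimate was under the preset 0.01 for NRF2 targets (0.0022), the unfolded protein response (0.0024), glutathione genes (-0.0072) and p53 targets (-0.025). It was above 0.01 for the other called lists. Camera's unadjusted p still rose for NRF2 targets, from 8.53e-13 to 0.00138, and for the other lists under 0.01. A higher correlation therefore does not account for the weaker result of those lists. By fry 25 lists were called, 16 higher and 9 lower, and the cause of these differences was not tested further. The direction of a value, or of a list's test, turned for FTL with library size alone (0.0105), blood and endothelial markers without the filter on low counts (0.281), FOXO targets with at least 5 CPM (median -0.016), glutathione genes without shared genes (-0.0793, fewer genes), and by fry for selenoproteins (median -0.135), fatty acid oxidation and PPARA targets (-0.167) and FOXO targets (-0.110); the cause was not tested for the others. Counting each list and setting, 11 medians in 6 lists took another sign. Besides the blood and endothelial median without the filter and the glutathione median above, these were ferroptosis drivers (0.018 with library size alone, 0.217 without the filter), G2 and M phase (0.031 with library size alone, and without control replicate 1 or tamarixetin replicate 3), mesenchymal markers (without control replicate 3 or tamarixetin replicate 2), blood and endothelial markers (0.0032 with library size alone) and ribosomal proteins (-0.011 with upper quartile scaling). Every other count of genes or lists stayed within 1.5 times its value. The number of changed genes was 4560 at an adjusted p of 0.01, 4704 with DESeq2, which gave no adjusted p for 29012 genes, 5747 with limma-voom, and 5155 to 5367 with 1 library left out. No gene called in both took the opposite sign under any setting tried, and 17 axis genes changed wherever that set was recomputed.

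The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.0089, -0.041 and -0.020. With the number as a block 5735 genes changed, 5687 of them shared, and 15 lists, those of glutathione genes (camera adjusted p = 0.0694) and p53 targets (0.0634) no longer passing.

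Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes and 1 as many lists, the real one each time; 10 splits are too few for a share under 0.05. The real split gave 5771 genes and 17 lists, the highest other split 0 genes (edgeR; 136 to 184 genes at an unadjusted p under 0.05) and 10 lists. Each of the 9 others keeps an excess of control libraries on one side and mixes both groups on each side. The difference between the groups then adds to the spread within each side, so the 0 genes do not measure how many calls chance gives. On simulated counts 92% of 2-fold changes and 68% of 1.5-fold changes were recovered, so small changes are missed more often than large ones. The simulation changed 200 genes, while 5771 were called in the data. With more genes changed the adjustment is less strict, so the recovered shares may be too low for these data.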

Other observations

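The gene lists in this part were written after the values of single genes had been seen and were adjusted over 6 lists, so their p-values describe genes that could be picked for their values; the tests on RNR1, cholesterol synthesis and serum were chosen after their results were seen. Ligands and feedback regulators of the EGF receptor rose in 10 of 12, with a median log2 fold change of 1.08 (camera adjusted p = 1.39e-06; adjusted p = 0.0453 with an estimated correlation). The ligands EREG, AREG and HBEGF rose by 2.41, 2.28 and 1.66, and the receptor's negative regulator LRIG1 (-1.33) fell. EREG had low counts, at 0.957 CPM in control. Of the EGF receptor list, 3 members also stand in lists fixed earlier. Coagulation and complement factors, most of them secreted by hepatocytes, fell in 18 of 26 and rose in 2, MBL2 (2.22) and F11 (0.80), with a median of -0.62 (camera adjusted p = 1.39e-06; adjusted p = 0.0263 with an estimated correlation); C8A (-1.73) and F7 (-1.02) were lower, and 4 members also stand in lists fixed earlier.

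Bile acid genes fell in 9 of 13 and rose in 1, with a median of -0.48 (camera adjusted p = 8.99e-04; adjusted p = 0.0453 with an estimated correlation), and 2 members also stand in lists fixed earlier. CYP7A1, the rate-limiting enzyme of bile acid synthesis, fell by 2.20 on the log2 scale (SE 0.567) and the bile acid receptor NR1H4 by 1.60, while the exporter ABCC3 rose by 1.11.

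GPX4 was lower while SLC7A11 and most NRF2 targets were higher. The choice among 5 scalings does not account for it: the log2 fold change of GPX4 nearest to 0 was -0.29 (SE 0.043). These scalings moved the median of all genes only between -0.035 and 0.035. They could not show a change in total RNA per cell. The mRNAs of GPX1, SELENOH, MSRB1 and SELENOW fall when selenium is short. Of these 4, 3 were lower: GPX1 (-0.14, adjusted p = 0.0493 in edgeR's test), SELENOH (-0.46) and MSRB1 (-0.30). SELENOW stood at 0.045 and did not pass. GPX4 (-0.33) lay between GPX1 and SELENOH. These 4 genes do not show if a short supply of selenium lowers GPX4 mRNA itself, and they split. A short supply of selenium therefore stays undecided as an explanation. An effect of tamarixetin on GPX4 transcripts by another route was not tested.

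RNR1 was 2.96-fold lower, a larger fall than that of RNR2 and the coding genes. A lower amount of all mitochondrial transcripts would move the other genes alike, but the median of RNR2 and the coding genes (14 genes) was -0.28 with an SD of 0.20. The choice among the 5 scalings does not account for the fall of RNR1 either, with -1.53 as the value nearest to 0. A change in processing, stability or adenylation of RNR1, or in how the 3′ kit primes it, may lie behind it, and these were not tested; the rise of TRNF next to it and the fall of 5 mitochondrial tRNA genes are values such a test would have to cover.

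Cholesterol synthesis genes fell together. Less serum in the tamarixetin medium than in the control medium, which the labels leave open, would raise these genes, and their median was -0.56. Over 5 scalings the median nearest to 0 was -0.53. A sterol-rich state of the treated cells, or repression by the compound, may be behind the fall and stays untested. Less serum would lower immediate early and ribosome biogenesis genes, but their medians were 0.87 and 0.41, the opposite direction. That check was chosen after these medians were seen, and whether serum still acts on these genes at 24 h was not tested. It therefore does not exclude a serum difference. G1 and S genes, which less serum would also lower, fell (median -0.39). There a serum difference cannot be told apart from an effect of the compound, since the serum of the controls is not stated.

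Hypotheses on signalling were tested on the same data. CCN1 and AREG are known to respond to YAP, and CCN1 also to SRF. YAP and TEAD targets rose in 8 of 21 and fell in 5 (camera adjusted p = 0.121). CCN1 (2.26), AXL (1.59) and GADD45B (1.58) were among the 8 that rose. ARHGEF17 (-0.88), PTPN14 (-0.48) and CCN2 (-0.20) were among the 5 that fell. Although under 0.5 of the list rose, the bound set for excluding YAP and TEAD activity, a missed threshold over members that go both ways excludes nothing, so it stays open. Genes of the actin cytoskeleton and SRF targets rose in 17 of 25 and fell in none (camera adjusted p = 2.99e-07; adjusted p = 0.0263 with an estimated correlation), with ACTN1 (0.92), FLNA (0.81) and ACTG1 (0.57). That list was written after gene values had been seen, so its p does not decide on SRF activity, which also stays open.

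Loss of microtubules is known to lower the mRNAs of alpha and beta tubulins through the free subunits. The most abundant tubulin genes, TUBB (-0.35) and TUBA1B (-0.29), fell, and the summed mean of 10 tubulin genes went from 6558 to 5707 CPM. A fall of all of them would include the next most abundant, but TUBA1C, at 1011 CPM in control, rose by 0.088 (SE 0.032), and TUBB4B (-0.027, SE 0.038) and TUBB3 (-0.041, SE 0.043) did not pass the test. In all 20% of the 10 genes fell and 5 rose, 4 of these from under 50 CPM, which speaks against a fall of all tubulin mRNAs; one limited to TUBB and TUBA1B stays open.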
